A study of Mus musculus with 26 samples.

How the data were processed

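Total RNA from tibialis anterior and extensor digitorum longus muscle (TA/EDL) of 26 mice was measured on 1-colour Affymetrix expression arrays, 1 array per mouse. Per the labels' protocols, the RNA was extracted with Trizol, cleaned on columns, and copied into biotin-labelled cRNA. Mice carried either floxed alleles (FLOX) or a knockout of PGC-1a limited to skeletal muscle (MKO), and were FLOX and MKO littermates of mixed C57/BL6 and 129 background housed singly. Per the labels' protocols, food intake with free access was recorded for at least 10 days, and mice were then divided at random between the diets. Control mice received 90% of that intake. Calorie-restricted (CR) mice received 80% for the first week and then a diet made for 40% restriction, fed at 60% of that intake, for about 11 weeks. The 4 groups held 6 FLOX and 7 MKO mice on the control diet and 6 FLOX and 7 MKO mice on CR, as the titles of the arrays give them.

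The deposited table held 1 intensity per probe set and array, processed by the authors, for 45101 probe sets. The values were on a linear scale and none was at or below 0. How the authors computed these intensities, including background correction, summary over probes and normalization between arrays, is not given in the sources used here. The lowest value of an array lay between 56.6 and 62.8, its median between 212 and 232, and its highest value between 37243 and 38435. A floor near 60 on every array means that fold changes of dim genes are compressed toward 0. No detection calls and no scan dates were used, so neither a background limit per array nor a scan batch could be tested. The number of arrays limits the precision of every value.

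From the deposited intensity, log2(intensity + 16) was computed, and every fold change is on that scale, which understates the change of dim genes. No further normalization between arrays was applied in the reported values. Of the probe sets, 64 were controls, 34945 named exactly 1 gene in the platform annotation, 932 named several genes and 9160 named none. Only those naming 1 gene were used. The symbols of 34741 were updated through their gene identifiers and 204 kept the symbol of the annotation. Probe sets whose mean over all arrays was under the 30th percentile (log2 value 7.47) were left out. For each gene the passing probe set of highest mean was taken, which left 14854 genes. For 6584 of these genes several probe sets passed. For 1311 genes the probe set taken has a suffix (_s_at or _x_at) that marks probes able to bind several transcripts.

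Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group over all 26 arrays, so that all comparisons share 1 estimate of the spread. The comparisons were CR against control diet in FLOX, the same in MKO, MKO against FLOX on the control diet, the same on CR, and the interaction, which is the diet effect in MKO minus that in FLOX. P-values were adjusted by the Benjamini-Hochberg method over the 14854 genes, and a gene was called changed at an adjusted p under 0.05. Adjusted p-values of single genes come from this limma fit. There were 33 gene lists, for mitochondrial functions, fuel use, fibre type, signalling, stress and markers of cells other than muscle fibres. Of their 793 memberships 711 were tested, 24 lay under the filter and 58 had no probe set naming that gene alone and were not analysed here. Lists with at least 5 tested genes, 32 of the 33, were tested with limma's fry, adjusted over the 32 lists. The fry test asks whether the members move, on balance, one way, and does not compare the list with other genes. Camera, which does compare a list with the other genes, was run with a preset correlation of 0.01 and with an estimated correlation. The median of a list is given with a bootstrap 95% interval over its members (10000 resamples). A score of the mitochondrial respiratory chain (OXPHOS) was the mean log2 value of the tested members of its 4 lists, and was compared between groups with exact two-sided permutation tests of mice.

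The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Ppargc1a always. For CR in FLOX and for MKO on the control diet it names the 8 largest rises and the 8 largest falls among changed genes, and for CR in MKO and MKO on CR the 5 largest of each. Where no gene passes for the interaction, it names the 5 genes of smallest p as not passing. For each list called in a comparison it names the 2 members of smallest p. Predicted genes and gene models without a proper symbol are counted but not named. By this rule 111 genes are named.

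Alternatives changed the pseudocount to 1 or 64, the filter to none or the 50th percentile, the normalization to quantile or median centring, the choice of probe set, the variance model, the weights of arrays, the arrays in the fit, the thresholds and the list test. Each mouse was also left out in turn, and the number in the array title was added as a block. After the data were seen, 2 alternatives were added: leaving out 2 arrays rich in slow muscle transcripts, defined as a mean log2 value of Myh7, Tnni1 and Tnnt1 more than 0.8 above the median of the group, and an index of clock genes as a covariate. The index is the mean of 6 genes on the side of Dbp minus that of 3 on the side of Arntl, all members of the clock list. Other splits of the same mice, 100 per comparison with the real one included, show what counts other groupings give.

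The procedure was tested on simulated data with 14854 genes and the group sizes used here. For each comparison 67, 67 and 66 genes were changed by 0.25, 0.5 and 1, with noise independent between genes. At a simulated change of 0.25 on the log2 scale it recovered 70.1% of changed genes for CR in FLOX, 76.1% for CR in MKO, 58.2% for MKO on the control diet, 68.7% for MKO on CR and 25.4% for the interaction. At a change of 0.5 it recovered 95.5%, 95.5%, 97.0%, 94.0% and 85.1%, in the same order. Of 10 simulated lists of 30 genes shifted by 0.2 in the comparison of CR in FLOX, 10 were called, and of 20 unshifted lists 0 were called. Figures were drawn with matplotlib 3.10.9.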

Results

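The series measured gene expression in TA/EDL, the fast muscles at the front of the lower leg, of 26 mice in a design with 2 diets and 2 genotypes. There were 6 FLOX and 7 MKO mice on the control diet and 6 FLOX and 7 MKO mice on CR. PGC-1a, the product of Ppargc1a, is a transcriptional coactivator of mitochondrial genes. The title of the series asks whether PGC-1a in muscle carries the mitochondrial and the metabolic changes of calorie restriction, so the diet effect was measured in each genotype, the genotype effect on each diet, and the difference between the diet effects was tested itself. Arrays of the same group correlated at 0.984 to 0.996 over the 14854 genes tested, and no 2 arrays held identical values.

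The targeted gene was read in every mouse first. All 5 probe sets for Ppargc1a were brighter, not dimmer, in the mice labelled MKO, by 1.53- to 1.76-fold on the control diet and by 1.34- to 1.57-fold on CR. On the control diet the brightest of them had an intensity of 911 ± 67.3 (SD, n = 6) in FLOX mice and 1542 ± 372 (SD, n = 7) in mice labelled MKO. On CR it was 1104 ± 189 (SD, n = 6) and 1674 ± 160 (SD, n = 7). The limma adjusted p over all probe sets was 4.12e-05 on the control diet and 0.0003 on CR. No mouse labelled MKO lay within the range of the FLOX mice on the control diet for any of the 5 probe sets, and on CR 4 of the values did. The place of these probe sets relative to the deleted part of the gene is not given in the sources used here, and a probe outside the deleted part checks nothing. While their place is unknown, brighter probe sets do not bear out the label and cannot be counted against it either. The mice are called "labelled MKO" throughout. CR was followed by a higher signal in 2 of the 5 probe sets in FLOX mice and in 0 in mice labelled MKO at an adjusted p under 0.05, and the interaction passed for 0. For the probe set tested as the gene's, the log2 change under CR was 0.26 in FLOX (adjusted p = 0.159) and 0.14 in mice labelled MKO (adjusted p = 0.425). Without control-diet MKO mouse 3 the same changes were 0.26 and 0.25 with adjusted p of 0.0436 and 0.0366.

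**Figure D1:**
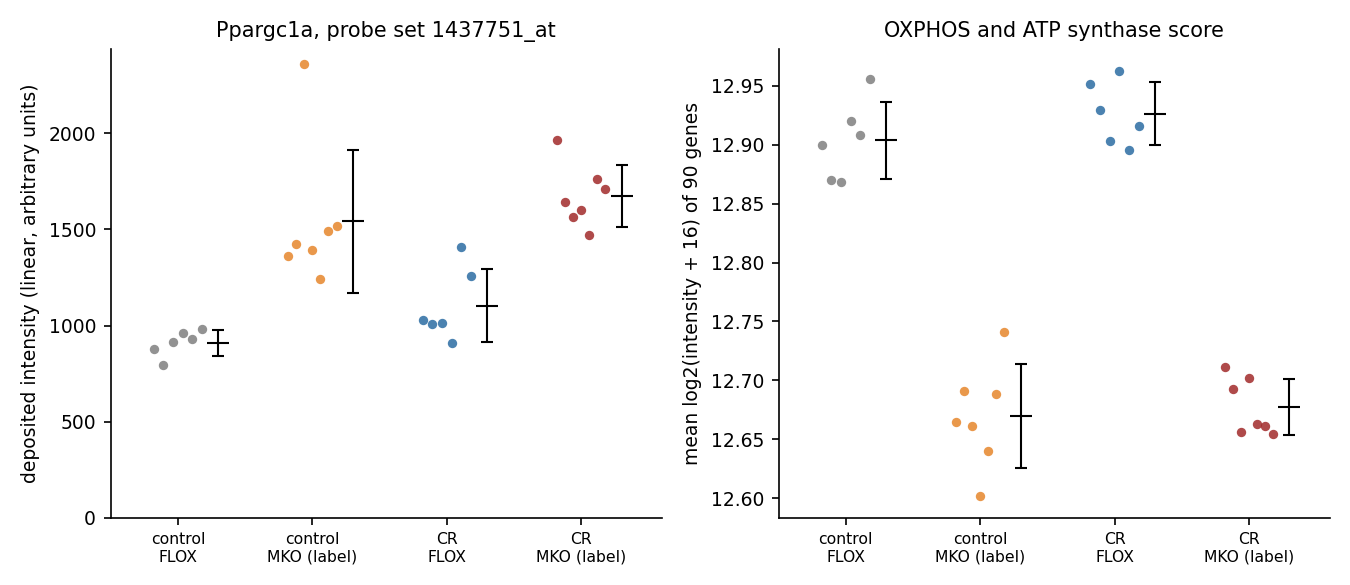
Left, deposited intensity of the brightest Ppargc1a probe set in each mouse; right, the OXPHOS score, the mean log2(intensity + 16) of 90 respiratory chain and ATP synthase genes (axis not starting at 0). Points are mice and bars the mean ± SD of the 4 groups, and within each diet the mice labelled MKO lie above the FLOX mice on the left and, at means of 12.67 and 12.68 against 12.90 and 12.93, below them on the right.

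In FLOX mice, CR was followed by lower transcripts of 20 of 28 extracellular matrix genes and 9 of 15 fibroblast and tendon markers, and by higher transcripts of 4 of 18 neuromuscular junction and 23 of 64 mitochondrial ribosome genes. Each of these 4 lists passed with fry and lost the call with an estimated correlation (adjusted p = 0.0893, 0.0893, 0.0975 and 0.235). Among the collagens, Col3a1 fell from 3356 ± 491 (SD, n = 6) to 1383 ± 541 (SD, n = 6), 2.57-fold lower (log2 change -1.36 ± 0.24 SE, adjusted p = 0.000537), and Col1a2 fell 2.27-fold (adjusted p = 0.000744). In both cases the 6 CR mice lay below all 6 control mice. The largest fall was that of Mss51, a muscle protein linked to mitochondria, from 4600 ± 1090 (SD) to 792 ± 333 (SD), 6.06-fold lower (log2 change -2.60 ± 0.25 SE, adjusted p = 3.89e-07). The largest rise was that of Actc1, cardiac alpha-actin, from 3775 ± 1723 (SD) to 16355 ± 5657 (SD), 4.51-fold higher (log2 change 2.17 ± 0.38 SE, adjusted p = 0.000485).

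Of the 14854 genes, 1490 changed under CR in FLOX mice, 692 upward and 798 downward, and 109 of these changed by at least 0.5 on the log2 scale. The other large rises were Mybph, a myosin-binding protein (2.81-fold), Egln3, a prolyl hydroxylase of the hypoxia pathway (2.24-fold), Ppp1r1a, an inhibitor of protein phosphatase 1 (2.06-fold), Zfp503 (2.04-fold), Casq2, the calsequestrin of cardiac and slow muscle (1.99-fold), Sh3rf2 (1.92-fold) and Peg3, an imprinted zinc-finger gene (1.88-fold). Their adjusted p ranged from 3.38e-06 for Ppp1r1a to 0.00178 for Egln3. The other large falls were Cd74, the invariant chain of MHC class II (2.82-fold), Chac1, which degrades glutathione (2.72-fold), Mrln, a micropeptide that inhibits the calcium pump of the sarcoplasmic reticulum (2.37-fold), Pla2g7 (2.25-fold) and Aplnr, the apelin receptor (2.24-fold). The weakest of these was Chac1 (adjusted p = 0.00849), for which 3 of the 6 CR mice lay below every control mouse.

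By list, 10 of the 32 lists changed on balance in one direction. In the extracellular matrix list 0 members rose, 20 fell and 8 did not pass, of 28 tested (fry adjusted p = 0.000177, 23 fell when adjusted over the list alone). Its median log2 change was -0.47. Serpinh1, the collagen chaperone, fell 1.77-fold (adjusted p = 3.26e-07) and Col4a1, a basement membrane collagen, 1.75-fold (adjusted p = 2.15e-05). The list had an adjusted p = 0.0893 with an estimated correlation. Markers of other cells moved with it. Of 15 fibroblast and tendon markers 0 rose and 9 fell (fry adjusted p = 0.000226, 11 fell adjusted over the list alone, adjusted p = 0.0893 with an estimated correlation), among them Thy1 by 1.30-fold and Chad by 1.73-fold. Of 25 endothelial markers 0 rose and 3 fell (fry adjusted p = 0.0241, 5 fell adjusted over the list alone), with Cd34 1.32-fold and Emcn 1.16-fold lower. Of 24 macrophage and leukocyte markers 1 rose and 4 fell (fry adjusted p = 0.0445, the same counts adjusted over the list alone), with Cd74 and the MHC class II gene H2-Ab1, 2.18-fold lower, as the members of smallest p. The adjusted p with an estimated correlation was 0.415 for the endothelial and 0.488 for the macrophage list.

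Among mitochondrial and muscle lists in FLOX mice, 23 of 64 mitochondrial ribosome genes rose and 1 fell (fry adjusted p = 0.00195, 33 rose and 3 fell adjusted over the list alone), including Mrps2 by 1.25-fold and Mrps30 by 1.18-fold. Of 18 neuromuscular junction genes 4 rose and 0 fell (fry adjusted p = 0.000609, 8 rose adjusted over the list alone), with Chrna1, the alpha subunit of the acetylcholine receptor, 1.37-fold and the transcription factor gene Etv5 1.25-fold higher. Of 25 genes of mitochondrial import, dynamics and mitophagy 3 rose and 0 fell (fry adjusted p = 0.0445, 5 rose adjusted over the list alone), with the fission gene Dnm1l 1.22-fold and the import gene Timm44 1.16-fold higher. Of 14 sirtuin and NAD genes 3 rose and 0 fell (fry adjusted p = 0.0385, 3 rose and 1 fell adjusted over the list alone), with Sirt5 1.20-fold and Nnt, the mitochondrial transhydrogenase, 1.41-fold higher. Nnt passed less firmly than Sirt5, and without control-diet FLOX mouse 2 its adjusted p was 0.0501. Of 25 heat shock genes 0 rose and 4 fell (fry adjusted p = 0.0113, 5 fell adjusted over the list alone), with the chaperones Dnaja1 and Hsp90aa1 1.36- and 1.31-fold lower. Of 20 genes of glucose uptake and glycogen 1 rose and 3 fell (fry adjusted p = 0.0297, 2 rose and 6 fell adjusted over the list alone). The 2 of smallest p moved apart, Phka1, a subunit of phosphorylase kinase, 1.26-fold lower and Gbe1, the glycogen branching enzyme, 1.47-fold higher. The adjusted p with an estimated correlation was 0.235 for mitochondrial ribosomes, 0.0975 for the neuromuscular junction, 0.401 for heat shock and 0.488 for each of the other 3 lists.

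The number of lists called for CR in FLOX fell to 0 with an estimated correlation, to 6 without the arrays rich in slow muscle transcripts or with the clock covariate (both chosen after the data were seen), to 5 without control-diet FLOX mouse 1, and to 6 without control-diet FLOX mouse 2 or 3 or CR FLOX mouse 3. The endothelial call was lost without control-diet FLOX mouse 1 or 5 or CR FLOX mouse 3 (adjusted p up to 0.0651), the glucose call without control-diet FLOX mice 1 to 3 or CR FLOX mice 1 to 4, each alone (up to 0.0687), and the sirtuin call without control-diet FLOX mice 1 to 4 or CR FLOX mice 1, 2, 5 or 6, each alone (up to 0.144). Leaving out any of 17 mice ended the macrophage and the mitochondrial import calls (adjusted p up to 0.144 for each): control-diet FLOX mice 1 to 5, control-diet MKO mice 6 and 7, CR MKO mice 2 to 5 and 7, CR FLOX mice 1, 3, 5 and 6, and CR FLOX mouse 4 for macrophages or 2 for import. Without control-diet FLOX mouse 6 complex IV, the ATP synthase and the TCA cycle lists passed upward (adjusted p of 0.0299, 0.0355 and 0.0413), and without CR FLOX mouse 1 inflammation passed downward (0.0339). Without the arrays rich in slow muscle transcripts 5 of the calls were lost and the slow fibre list passed upward (0.03). Those arrays were picked by Myh7, Tnni1 and Tnnt1, which are members of the slow fibre list. Leaving out a high control array raises the change of that list by construction, so its result says nothing on its own.

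In the mice labelled MKO, CR was followed by lower transcripts of 23 of 28 extracellular matrix genes, and the list's call was lost with an estimated correlation (adjusted p = 0.153). The largest falls were those of Mss51, Cd74, Col3a1, Pdk4 and Col1a2. Col3a1 fell from 2841 ± 794 (SD, n = 7) to 919 ± 264 (SD, n = 7), 3.06-fold lower (log2 change -1.61 ± 0.22 SE, adjusted p = 1.92e-05), with 7 of 7 CR mice below every control mouse. Mss51 fell 4.71-fold (adjusted p = 4.54e-07), Cd74 3.07-fold (adjusted p = 2.69e-05) and Col1a2 2.42-fold (adjusted p = 8.48e-05). Pdk4, the kinase that switches off pyruvate dehydrogenase, fell 2.85-fold (adjusted p = 0.00485), and 4 of 7 CR mice lay below every control mouse. The largest rises were Casq2 (2.96-fold, from 635 ± 188 to 1870 ± 293, SD, adjusted p = 2.04e-07), Egln3 (2.50-fold), Mid1ip1, which promotes fatty acid synthesis (2.27-fold), the metallothionein Mt1 (2.13-fold) and Fkbp5, a glucocorticoid-responsive chaperone (1.87-fold), with adjusted p up to 0.00029.

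In all, 2246 genes changed under CR in the mice labelled MKO, 986 upward and 1260 downward, 128 of them by at least 0.5 on the log2 scale. Of the 32 lists 8 changed. In the extracellular matrix list 0 members rose and 23 of 28 fell (fry adjusted p = 1.97e-05, 24 fell adjusted over the list alone, adjusted p = 0.153 with an estimated correlation), with Serpinh1 1.63-fold and Col4a1 1.75-fold lower. Of 15 fibroblast and tendon markers 0 rose and 11 fell (fry adjusted p = 0.000232, 12 adjusted over the list alone), including Thy1 by 1.29-fold and Tnmd, a tendon gene, by 1.63-fold. Of 25 endothelial markers 0 rose and 11 fell (fry adjusted p = 0.00135, 13 adjusted over the list alone), including Angpt1 by 1.38-fold and Kdr, a receptor for VEGF, by 1.41-fold. Of 25 inflammation and interferon genes 1 rose and 11 fell (fry adjusted p = 0.0242, 12 fell adjusted over the list alone), with the MHC class I genes B2m and H2-K1 1.40- and 1.42-fold lower. With an estimated correlation the adjusted p was 0.191, 0.321 and 0.643 for these 3 lists in turn.

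The lists that moved upward under CR in the mice labelled MKO had few members past the threshold. Of 64 mitochondrial ribosome genes 15 rose and 2 fell (fry adjusted p = 0.0331, 20 and 2 adjusted over the list alone). The 2 of smallest p moved apart, Mrpl2 1.19-fold higher and Mrps12 1.18-fold lower. Of 25 mitochondrial import genes 5 rose and 0 fell (fry adjusted p = 0.039, 6 rose and 1 fell adjusted over the list alone), including the import gene Timm17a by 1.12-fold and the prohibitin Phb2 by 1.20-fold. Of 18 neuromuscular junction genes 2 rose and 0 fell (fry adjusted p = 0.0242, the same adjusted over the list alone), Chrna1 by 1.26-fold and Etv5 by 1.17-fold. Of 20 circadian clock genes 4 rose and 1 fell (fry adjusted p = 0.0298, the same adjusted over the list alone), with the clock repressors Cry2 and Per2 1.25- and 1.16-fold higher. With an estimated correlation the adjusted p was 0.643 for mitochondrial ribosomes, the neuromuscular junction and the clock, and 0.647 for mitochondrial import. With the probe sets of a gene averaged, Etv5 (adjusted p = 0.104) and Per2 (adjusted p = 0.0604) no longer passed.

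The 8 lists became 0 with an estimated correlation and 3 with the clock covariate, and the mitochondrial ribosome and import calls were lost without the arrays rich in slow muscle transcripts (adjusted p = 0.0695 for each). The clock index itself rose by 0.40 under CR in these mice, so this covariate may take out part of the diet effect. The 8 lists became 4 without control-diet MKO mouse 4 or CR MKO mouse 7, and 5 without CR MKO mouse 1, 2, 4 or 6. The inflammation call was lost without control-diet MKO mouse 4 (adjusted p = 0.0547), and the neuromuscular junction call without control-diet MKO mouse 3 or CR MKO mouse 1 or 7 (up to 0.0566). The clock call was lost without control-diet MKO mouse 1, 2 or 4 or CR MKO mouse 2, 4, 5, 6 or 7 (up to 0.0683), and the mitochondrial ribosome call without control-diet MKO mouse 3, 4 or 5 or CR MKO mouse 1, 2, 4, 6 or 7 (up to 0.0947). Leaving out any of 11 mice ended the mitochondrial import call (up to 0.0974), namely control-diet FLOX mouse 1, control-diet MKO mice 1, 4 and 5 and every CR MKO mouse.

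**Figure D2:**
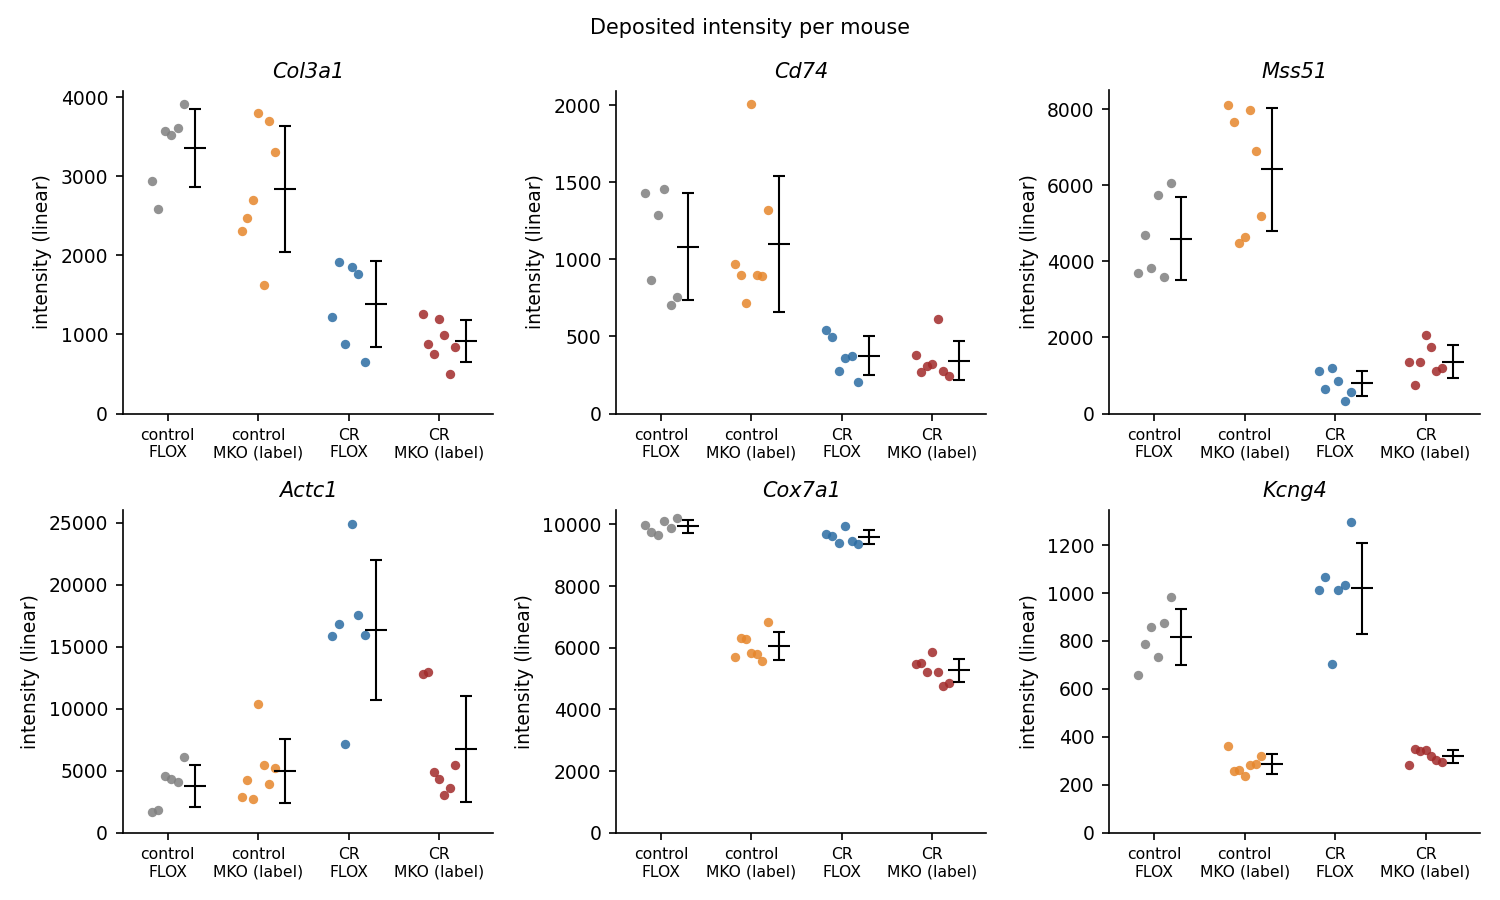
Deposited intensity (linear, from 0) of 6 genes in each mouse, with points for mice and bars for the mean ± SD of the 4 groups. Col3a1, Cd74 and Mss51 are lower on CR in both genotypes, Actc1 is high in CR FLOX mice, and Cox7a1 and Kcng4 are lower in the mice labelled MKO on both diets.

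On the control diet, the mice labelled MKO had lower transcripts of the respiratory chain, the TCA cycle and fatty acid oxidation than FLOX mice. All directions here rest on labels that the Ppargc1a probe sets did not bear out, though the place of these probe sets in the gene is unknown. Cox7a1, the muscle subunit of complex IV, was 1.64-fold lower (log2 change -0.72 ± 0.05 SE, adjusted p = 1.74e-11) and Atp5g1, of the ATP synthase, 1.48-fold lower (adjusted p = 2.2e-10). The largest falls among all genes were Kcng4, a potassium channel subunit, from 816 ± 115 (SD, n = 6) to 287 ± 43 (SD, n = 7), 2.75-fold lower (adjusted p = 2.07e-10), and Pnmal1, 2.41-fold lower (adjusted p = 0.000363). The largest rise was Gbp6, an interferon-inducible GTPase, from 490 ± 101 (SD) to 1347 ± 468 (SD), 2.64-fold higher (adjusted p = 1.01e-05). For each of these 5 genes all 7 mice labelled MKO lay beyond every FLOX mouse.

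Between these groups 2865 genes differed, 1345 higher and 1520 lower in the mice labelled MKO, and 167 by at least 0.5 on the log2 scale. The other large falls were Iqsec2 (2.37-fold), Gramd3 (2.21-fold), the glutamate receptor subunit Grik5 (2.20-fold), the calcium-binding S100a1 (2.17-fold), Myo7b (2.14-fold) and the carbonic anhydrase Car2 (2.09-fold), with adjusted p from 5.75e-15 for Car2 to 0.00192 for Myo7b. The other large rises were Myl3, the slow and ventricular essential light chain (2.36-fold), Csrp3, the muscle LIM protein (2.26-fold), Septin6 (1.78-fold), Eda2r, a receptor of the TNF family (1.75-fold), the potassium channel Kcnq5 (1.74-fold), the non-coding Hectd2os (1.71-fold) and Bex1 (1.67-fold). Ppargc1a was 1.65-fold higher (adjusted p = 2.46e-05 over genes). Csrp3 passed narrowly (adjusted p = 0.0462), 3 of 7 mice labelled MKO lay above every FLOX mouse, and leaving out any of 13 mice ended the call, with adjusted p from 0.0508 to 0.149. These were control-diet FLOX mice 2, 3, 5 and 6, control-diet MKO mice 2, 3, 6 and 7, CR FLOX mice 5 and 6 and CR MKO mice 2, 3 and 6. For Septin6 1 of 2 probe sets and for Kcnq5 2 of 3 had the same sign.

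Of the 32 lists 15 differed, 3 upward and 12 downward. Complex I had 31 of 34 members lower and 0 higher (fry adjusted p = 5.35e-10), complexes II and III 14 of 14 lower (3.61e-10), complex IV 15 of 19 lower and 1 higher (3.61e-10), the ATP synthase list 19 of 23 lower and 0 higher (1.73e-11), the TCA cycle list 19 of 20 lower and 0 higher (2.63e-11), and fatty acid oxidation 21 of 26 lower and 0 higher (2.51e-08). Adjusted over the list alone the lower members were 32, 14, 15, 21, 20 and 22. The slow fibre list was higher by a median of 0.29 but did not pass (fry adjusted p = 0.187). The median log2 difference of the 6 lists ran from -0.32 for fatty acid oxidation to -0.20 for the ATP synthase list. These 6 lists also passed with an estimated correlation, with adjusted p from 0.00247 to 0.0139. Examples are Ndufa8 (1.34-fold lower) and Ndufa4 (1.25-fold), Uqcrq (1.30-fold) and Cyc1 (1.20-fold), Sco2 (1.45-fold), the mitochondrial creatine kinase Ckmt2 (log2 difference -0.59), Got2 (1.54-fold) and Mdh2 (1.19-fold), and the beta-oxidation enzymes Acaa2 (1.57-fold) and Acadl (1.45-fold). In every one of these 10 genes 7 of 7 mice labelled MKO lay below all FLOX mice.

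Of 64 mitochondrial ribosome genes 31 were lower and 0 higher (fry adjusted p = 3.48e-05, 38 lower adjusted over the list alone), including Mrpl45 by 1.28-fold and Mrpl15 by 1.27-fold. Of 25 mitochondrial import genes 10 were lower and 0 higher (8.04e-05, 10 lower adjusted over the list alone), including Timm17a by 1.26-fold and Timm44 by 1.23-fold. Of 14 sirtuin and NAD genes 3 were lower and 0 higher (3.65e-06, 6 lower and 1 higher adjusted over the list alone), with the mitochondrial deacetylase Sirt3 1.58-fold and Sirt5 1.18-fold lower. Of 25 endothelial markers 9 were lower and 0 higher (0.000146, 11 lower adjusted over the list alone). Its member of smallest p, Vegfb, 1.87-fold lower, encodes a growth factor that muscle fibres themselves make, and the next, Gpihbp1, 1.30-fold lower, is a capillary protein. In the test with an estimated correlation the adjusted p was 0.155, 0.178, 0.157 and 0.178 for these 4 lists in turn.

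In 3 of the 5 remaining lists members passed in both directions, and in the atrophy and fast fibre lists upward alone. Of 22 reactive oxygen defence genes 2 were higher and 4 lower (fry adjusted p = 0.0213, 3 and 4 adjusted over the list alone), with Sod2, the mitochondrial superoxide dismutase, 1.45-fold and Prdx2 1.29-fold lower. Of 26 lipid synthesis and storage genes 2 were higher and 6 lower (0.0431, 2 and 8 adjusted over the list alone). The lipase Pnpla2 was 1.52-fold and the acyltransferase Dgat2 1.54-fold lower. Of 20 genes of glucose uptake and glycogen 6 were higher and 1 lower (0.000778, 7 and 1 adjusted over the list alone). Its members of smallest p moved apart, with Pdk2 1.34-fold lower and Phkb, a subunit of phosphorylase kinase, 1.30-fold higher. Of 27 atrophy and proteolysis genes 6 were higher and 0 lower (0.00497, the same adjusted over the list alone), including Cavin4 by 1.24-fold and the proteasome gene Psmd11 by 1.13-fold. Of 18 fast fibre genes 3 were higher and 0 lower (0.0148, the same adjusted over the list alone), with Cacng1 1.21-fold and Eya1 1.18-fold higher. With an estimated correlation the adjusted p was 0.75, 0.673, 0.0799, 0.188 and 0.529 for these 5 lists in turn, and 6 of the 15 lists passed in all. The lipid call was lost without control-diet FLOX mouse 2 or 3, control-diet MKO mouse 1, 5, 6 or 7 or CR FLOX mouse 2 (adjusted p up to 0.241), the reactive oxygen call without control-diet FLOX mouse 2 or 3 (adjusted p up to 0.0702) and the fast fibre call without control-diet FLOX mouse 5 (adjusted p = 0.0569). The slow fibre list passed upward without control-diet FLOX mouse 1 (fry adjusted p = 0.0315) and without both arrays rich in slow muscle transcripts (0.00766). The slow muscle transcripts of that mouse lay 1.44 on the log2 scale above the median of its group. These transcripts are members of the slow fibre list, so leaving out a high FLOX array raises this difference by construction. Neither result therefore says anything on its own. With the clock covariate the clock list passed upward (0.00249) and the fast fibre call was lost (0.0669). The covariate is made from members of the clock list, so the result of that list says nothing on its own. Glycolysis passed downward without CR FLOX mouse 4 (adjusted p = 0.0397).

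On CR, the mice labelled MKO differed from FLOX mice in the same mitochondrial lists, again with directions that rest on the labels. Kcng4 was 3.05-fold lower, at 319 ± 27.4 (SD, n = 7) against 1020 ± 189 (SD, n = 6) (log2 change -1.61 ± 0.11 SE, adjusted p = 1.74e-11). Actc1 was 2.65-fold lower (adjusted p = 0.00759), Iqsec2 2.64-fold, Mybph 2.54-fold (adjusted p = 1.63e-05) and Car2 2.54-fold (adjusted p = 1.65e-17). The largest rises were Csrp3 (2.58-fold), Myl2, the slow and ventricular regulatory light chain (2.39-fold), Gbp6 (2.17-fold), Pfkfb3, which makes an activator of glycolysis (2.00-fold), and Kcnq5 (1.84-fold). Ppargc1a was 1.52-fold higher (adjusted p = 0.000201). Csrp3 did not pass without CR FLOX mouse 4 (adjusted p = 0.0757), and Pfkfb3 (adjusted p = 0.0498) no longer passed on leaving out any of 18 mice, at adjusted p up to 0.148. These were control-diet FLOX mice 1 and 6, every control-diet MKO mouse, CR FLOX mice 2, 5 and 6 and CR MKO mice 1, 2, 3, 5, 6 and 7. For Myl2 3 of 7 mice labelled MKO lay above every FLOX mouse. CR MKO mouse 6 had slow muscle transcripts 2.49 on the log2 scale above the median of its group, and the slow fibre list was higher by a median of 0.32 but did not pass (fry adjusted p = 0.107).

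In total 2567 genes differed on CR, 1222 higher and 1345 lower in the mice labelled MKO, 152 by at least 0.5 on the log2 scale. Of the 32 lists 15 differed, 4 upward and 11 downward. Lower members, with 0 higher, were 30 of 34 in complex I (fry adjusted p = 3.63e-10), 13 of 14 in complexes II and III (8.19e-11), 15 of 19 in complex IV (4.11e-11), 19 of 23 in the ATP synthase list (1.61e-12), 20 of 20 in the TCA cycle list (7.82e-13), 23 of 26 in fatty acid oxidation (2.35e-08) and 31 of 64 in mitochondrial ribosomes (7.25e-07). Adjusted over the list alone they were 31, 14, 15, 23, 20, 23 and 35. The sirtuin and NAD list had 1 member higher and 6 lower (7.81e-09, the same adjusted over the list alone). These 8 lists and that of glucose uptake and glycogen passed with an estimated correlation, with adjusted p from 0.00103 to 0.0435. Examples are Ndufa8 (1.41-fold lower) and Ndufa4 (1.24-fold), Uqcrfs1 (1.23-fold) and Uqcrc1 (1.32-fold), Cox7a1 (1.82-fold) and Sco2 (1.59-fold), Atp5g1 (1.47-fold) and Atp5g3 (1.23-fold), Cs, the citrate synthase (1.40-fold), and Mdh2 (1.24-fold), Acaa2 (1.62-fold) and Echs1 (1.47-fold), Mrpl45 (1.49-fold) and Mrpl15 (1.34-fold), and Sirt3 (1.84-fold) and Sirt5 (1.37-fold).

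Of the other lists on CR, endothelial markers had 11 of 25 members lower and 0 higher (fry adjusted p = 8.11e-06, 16 lower adjusted over the list alone), with Vegfb 1.81-fold and Nos3 1.24-fold lower. Mitochondrial import had 8 of 25 lower and 1 higher (5.53e-05, 9 and 1 adjusted over the list alone), with the fusion gene Mfn1 1.57-fold and Timm44 1.27-fold lower. Reactive oxygen defence had 3 of 22 higher and 5 lower (0.0029, the same adjusted over the list alone), with Sod2 1.55-fold and Prdx2 1.29-fold lower. Upward, glucose uptake and glycogen had 6 of 20 higher and 2 lower (1.98e-05, the same adjusted over the list alone), with Phkb 1.29-fold and Gyg, glycogenin, 1.22-fold higher. The clock list had 5 of 20 higher and 0 lower (0.00121, the same adjusted over the list alone), with Rora 1.40-fold and Clock 1.29-fold higher. Heat shock had 6 of 25 higher and 1 lower (0.0063, the same adjusted over the list alone), with Hsp90aa1 1.20-fold and Dnaja1 1.18-fold higher. Atrophy and proteolysis had 5 of 27 higher and 0 lower (0.0253, the same adjusted over the list alone), with the protease Ctsl 1.36-fold and Psmd11 1.14-fold higher. With an estimated correlation the adjusted p was 0.0594 for endothelial markers, 0.168 for mitochondrial import, 0.675 for reactive oxygen defence, 0.0957 for the clock, 0.171 for heat shock and 0.298 for atrophy. The atrophy call was also lost with quantile normalization (adjusted p = 0.117), without the arrays rich in slow muscle transcripts (adjusted p = 0.0617), and without any of 5 mice, namely CR FLOX mice 1, 2 and 4 and CR MKO mice 5 and 6 (adjusted p up to 0.0862). The fast fibre list passed upward with quantile normalization (adjusted p = 0.00317) and without control-diet FLOX mouse 3 or 5, control-diet MKO mouse 4, CR FLOX mouse 5 or CR MKO mouse 4 (0.0362 to 0.0485), and with the clock covariate (0.0424). Adipocyte markers passed downward without control-diet FLOX mouse 3 (0.0489), and the neuromuscular junction without CR MKO mouse 1 (0.0133).

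**Figure D3:**
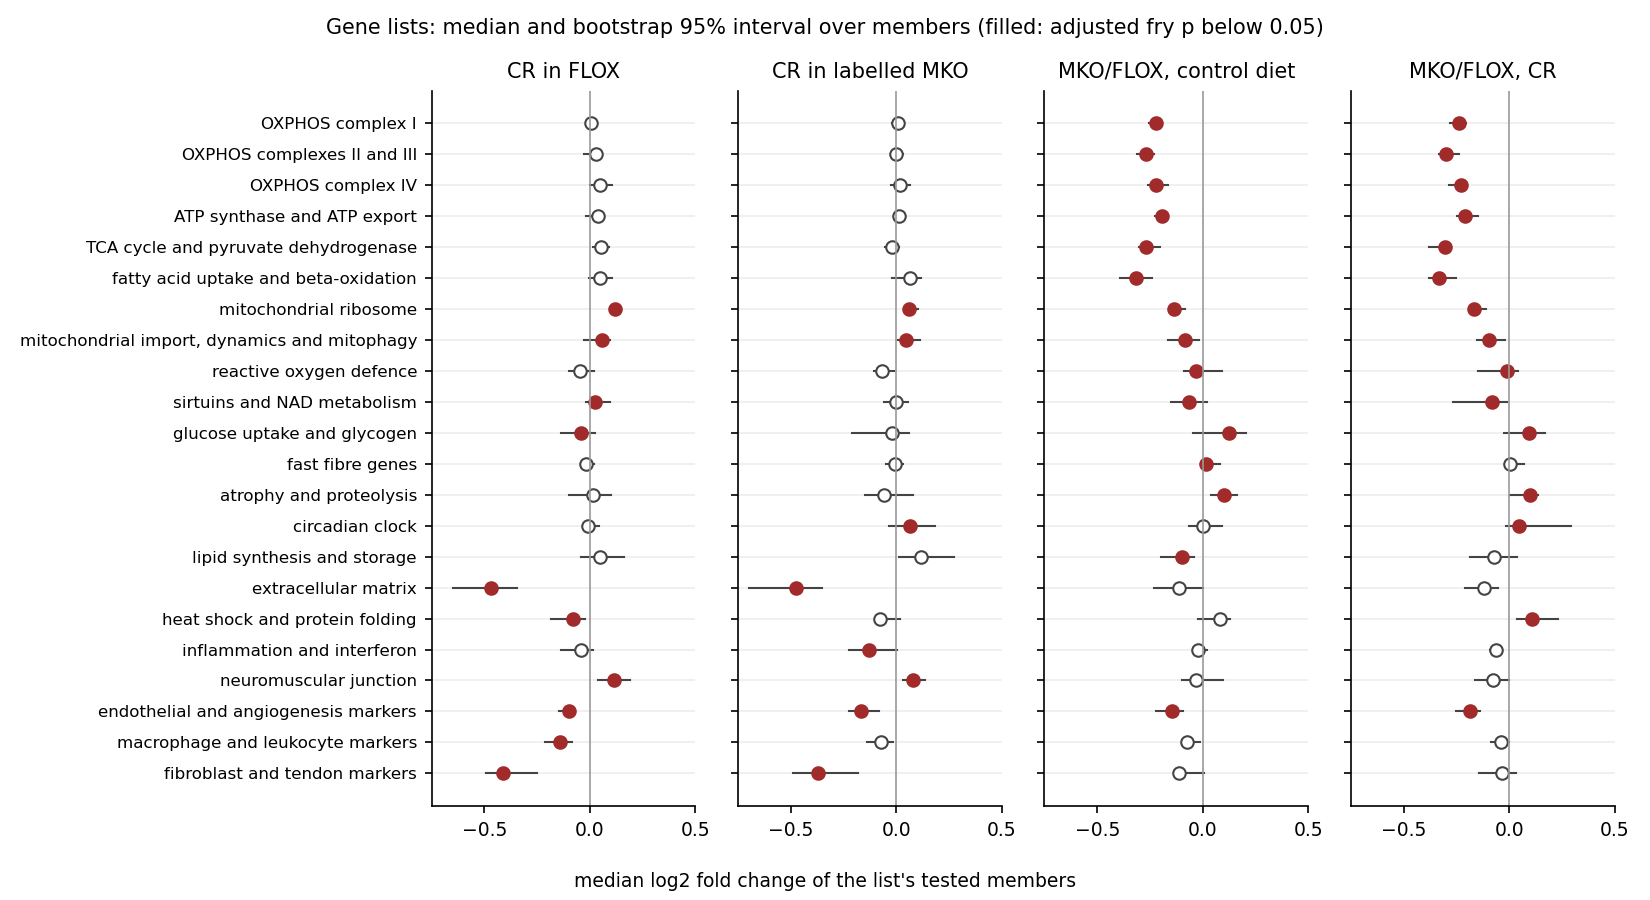
Median log2 fold change of the tested members of each list called in at least 1 comparison, with bootstrap 95% intervals over members and filled points for a fry adjusted p under 0.05. The extracellular matrix list lies at -0.47 under CR in both genotypes, and complexes II and III lie at -0.27 and -0.30 in mice labelled MKO on the control diet and on CR.

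Whether the diet effect differed between the genotypes was tested directly. No gene passed for the interaction by limma (smallest adjusted p = 0.389), and 720 genes had an unadjusted p under 0.05, where 743 are expected by chance. The 5 genes of smallest p did not pass: Kcnab1 (log2 difference -0.34 ± 0.07 SE), Mtfp1 (-0.31 ± 0.06) and Tm6sf1, Ube2k and Car2 (-0.28, 0.19 and -0.28), with adjusted p of 0.389 for the first 2 and 0.488 for the others. Actc1 and Mybph rose under CR in FLOX mice and had log2 changes of 0.35 (adjusted p = 0.577) and 0.29 (adjusted p = 0.346) in mice labelled MKO, but the differences themselves, -1.82 ± 0.52 (SE) and -1.20 ± 0.28 (SE), had adjusted p of 0.794 and 0.488. By fry 0 of 32 lists passed and 2 had an unadjusted p under 0.05. By camera with the preset correlation 3 did, those of the TCA cycle (adjusted p = 0.001), mitochondrial ribosomes (0.012) and heat shock (0.0475), and with an estimated correlation 0 did. On simulated data the same test recovered 85.1% of differences of 0.5 and 25.4% of differences of 0.25. Those data held 67 changed genes at each of these sizes and 66 at a change of 1, with noise independent between genes. Many true changes ease the adjusted threshold, so recovery would be lower if only a few genes differed. Small differences in the diet effect would therefore mostly not have been detected, and larger ones in few genes could also have been missed.

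The OXPHOS score gave 1 value per mouse. On the control diet it was 12.90 ± 0.033 (SD, n = 6) in FLOX mice and 12.67 ± 0.044 (SD, n = 7) in mice labelled MKO, a difference of -0.23 (bootstrap 95% interval -0.27 to -0.20, exact permutation p = 0.000583, the smallest the design allows). On CR the difference was -0.25 (-0.27 to -0.22, exact permutation p = 0.000583, again the smallest possible). On the linear scale these are changes of -15.0% and -15.8%. CR itself moved the score by 0.023 in FLOX mice (-0.0094 to 0.053, exact permutation p = 0.225) and by 0.0076 in mice labelled MKO (-0.026 to 0.042, exact permutation p = 0.704). The latter ran from -0.0048 without control-diet MKO mouse 4 to 0.020 without control-diet MKO mouse 7, so its sign is not settled. The adjusted p over these 4 comparisons were 0.00117, 0.00117, 0.3 and 0.704. The difference between the diet effects was -0.015 (-0.061 to 0.031, permutation p = 0.551 with 100000 resamples).

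Across the 14854 genes the diet effects in the 2 genotypes correlated at r = 0.75 (Spearman's rho 0.64) and the genotype effects on the 2 diets at r = 0.78 (rho 0.73). Genes are not independent replicates, so no p is given. The comparisons within each pair share no arrays. CR raised 405 genes in both genotypes and lowered 565 in both, where independent lists of these sizes would share 45.9 and 67.7, and 0 genes moved in opposite directions, against 112 for independent lists. The genotype effect was upward on both diets for 780 genes and downward on both for 853, against 111 and 138, with 1 gene opposite. Of the 1490 genes changed by CR in FLOX mice, 97.9% had the same sign in mice labelled MKO.

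**Figure D4:**
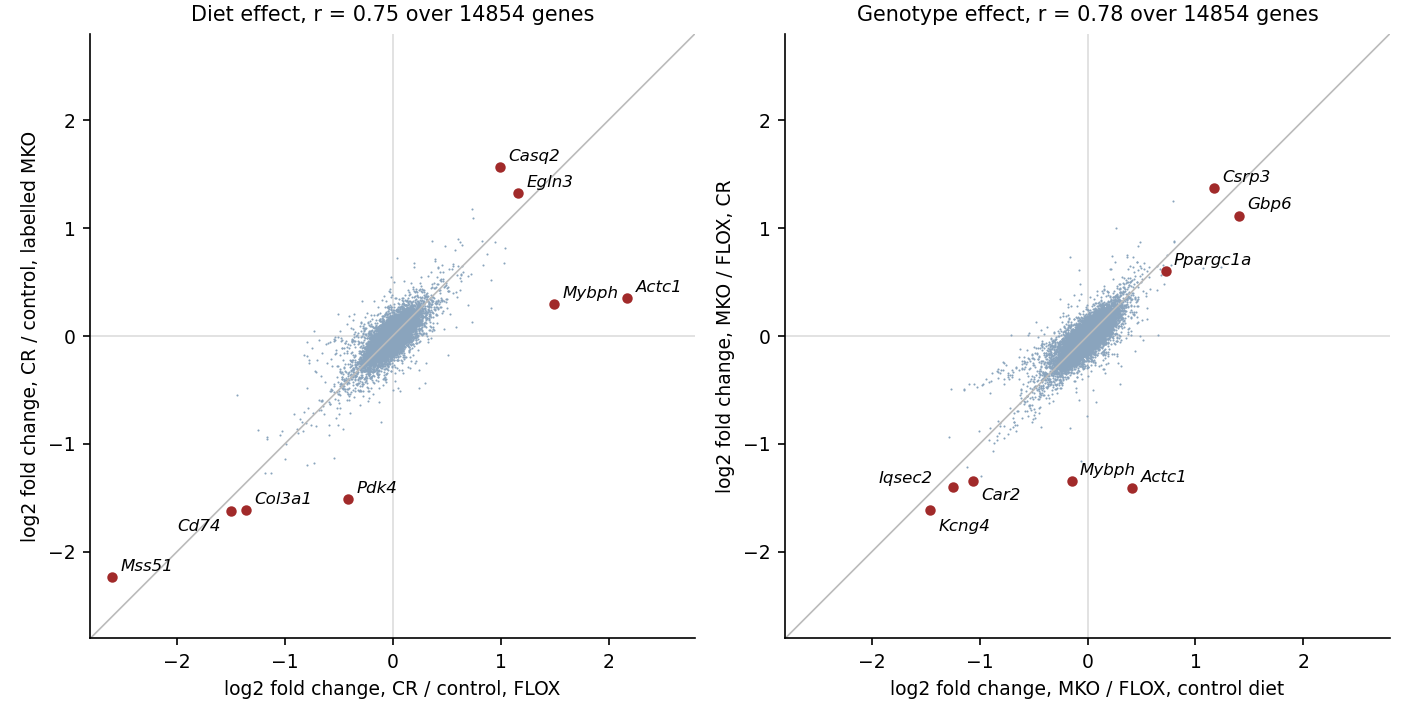
Log2 fold changes of 14854 genes (red, genes given by name in the panel; diagonal, equal effects): left, CR against control diet in FLOX mice (x axis) and in mice labelled MKO (y axis); right, mice labelled MKO against FLOX mice on the control diet (x axis) and on CR (y axis). The correlation is 0.75 on the left and 0.78 on the right, with Actc1 and Mybph off the diagonal in both panels.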

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

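A single mouse lay far from the rest of its group in 30 of 596 gap tests (Dixon) of named genes, lists and Ppargc1a probe sets in the 4 groups, and chance gives about 1 in 20 groups. Of what is weighed below, the tests for the matrix, for Ppargc1a, for slow muscle and for other cells were chosen after the result was seen, whereas the intensity trend, the added gene lists (apart from the MHC class II genes outside the fixed lists) and the other splits of the mice were written down before their own results. Distances below are on the log2 scale from the mean of the other mice of the group. Of these results 5 lay in control-diet MKO mouse 3 and 4 in CR MKO mouse 1.

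Among genes and lists of muscle fibres, slow fibre genes lay 0.80 higher and Myl2 1.65 higher in CR MKO mouse 6, Actc1 lay at -1.33 in CR FLOX mouse 3, and atrophy genes lay 0.21 higher in control-diet FLOX mouse 3. S100a1 was 0.16 higher in control-diet FLOX mouse 6. Chac1 was at -1.11 and Peg3 at 0.71 in CR MKO mouse 1, and Gbp6 at 1.02 in control-diet MKO mouse 4. Among mitochondrial genes and lists the distances were small: Acadl -0.26 in CR FLOX mouse 4, Atp5g1 -0.12 in CR MKO mouse 3, Echs1 0.18 in control-diet MKO mouse 7, Mdh2 0.05 (0.0516) in control-diet FLOX mouse 6, Ndufa4 0.04 (0.0359) in CR FLOX mouse 5 and mitochondrial ribosomes -0.12 in control-diet MKO mouse 4. Prdx2, of the reactive oxygen defence list, was at -0.13 in CR MKO mouse 5. Dnaja1 was at 0.24 in CR FLOX mouse 2 and the cell cycle list at 0.09 (0.0923) in CR FLOX mouse 4.

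Among markers of other cells, Emcn was at -0.10 in CR MKO mouse 3, Gpihbp1 at 0.31 in control-diet MKO mouse 7, Kdr at 0.25 in control-diet FLOX mouse 1 and Nos3 at 0.11 in control-diet FLOX mouse 2. Nerve and Schwann cell markers were at 0.26 in CR FLOX mouse 2 and red blood cell markers at 0.47 in control-diet MKO mouse 5.

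In control-diet MKO mouse 3 the Ppargc1a probe sets lay higher than in the other mice of the group, at 0.74 for the one tested as the gene's and 0.97, 0.96 and 0.70 for 3 others, and the list of PGC-1 family genes at 0.13 (0.125). In CR MKO mouse 1 2 of these probe sets lay at 0.32 and 0.34. Leaving out control-diet MKO mouse 3 moved the difference of Ppargc1a on the control diet from 0.72 to 0.62.

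The Ppargc1a probe sets were brighter in the mice labelled MKO, where a deletion would be expected to lower any probe inside it. An exchange of all labels would put the lower OXPHOS, ATP synthase and TCA genes, at a median of -0.22 in the mice labelled MKO, in the mice that carry PGC-1a, which goes against its known role. An exchange of single mice would leave some mice labelled MKO within the FLOX range, and 0 were, on either diet, for the brightest probe set and the OXPHOS score, although on CR 4 values of 2 dimmer probe sets lay in that range (CR MKO mice 2, 3 and 5). All 5 probe sets could lie outside the deleted part, and their place was not analysed here, so that no test of this could be made. A transcript that is truncated and made in larger amounts is a hypothesis that probe sequences and reads across the deleted part would test.

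The respiratory chain genes were lower in the mice labelled MKO. Less slow muscle in these samples would lower slow fibre genes, which were instead at 0.29 (interval over members 0.07 to 0.53) on the control diet. That list did not pass by fry. Its genes do not cover mitochondria-rich fibres of the fast type, and a smaller share of those was not tested. A trend of the fold change with signal intensity left the median at -0.23 once subtracted. More of other cells would raise their markers. On the control diet endothelial markers were at -0.14, macrophage markers at -0.07 and fibroblast and tendon markers at -0.11 (interval -0.13 to 0.008). The endothelial list holds Vegfb, which muscle fibres make, so it does not measure those cells alone. Nerve markers had a mean log2 of 8.50 ± 0.05 (SD) in mice labelled MKO against 8.46 ± 0.08 in FLOX mice. A larger share of some other cells is therefore not ruled out. That loss of PGC-1a in muscle fibres lowers these genes remains a hypothesis, which rests on the labels and was not itself tested here. The pattern was found and the alternatives weighed on the same arrays.

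Of 28 extracellular matrix genes 20 fell under CR in FLOX mice and 23 in the mice labelled MKO, and the list's call was lost with an estimated correlation (adjusted p = 0.0893 and 0.153). A smaller share of fibroblasts could account for it, since fibroblast and tendon markers outside the matrix list also fell, at a median of -0.41 (interval -0.49 to -0.25) against -0.47 for the matrix list in FLOX mice. A smaller share of every cell type other than muscle fibres would also lower nerve and Schwann cell markers, which were at -0.0014 (interval -0.045 to 0.099). Endothelial markers were at -0.10 in FLOX mice and -0.17 in the mice labelled MKO, and macrophage and leukocyte markers at -0.14 and -0.07. A smaller share of these cells, with a fall less than that of the matrix list, is therefore not ruled out. Nerve and macrophage markers were dimmer than the matrix genes, at mean log2 values of 8.46 and 8.72 against 9.97 in control-diet FLOX mice. Folds of dim genes are compressed toward 0, so a fall of these markers may be understated. A count of fibroblasts in sections would tell a smaller share from lower transcription per cell, which arrays of whole muscle do not separate.

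Other splits of the same mice into groups of the same sizes were made, 100 per comparison with the real one included. For the 4 pairwise comparisons 1 of 100 splits, the real one, gave as many genes and as many lists. A share below 1 in 100 cannot be resolved with 100 splits, so chance is bounded and not excluded. The real and the highest other count of genes were 1490 and 208 for CR in FLOX, 2246 and 635 for CR in MKO, 2865 and 2626 for MKO on the control diet and 2567 and 9 for MKO on CR. For lists they were 10 and 5, 8 and 6, 15 and 11, and 15 and 12. The split with 2626 genes kept 5 of the 6 FLOX mice together. Another split of that comparison that kept 5 of the 6 gave 140 genes, so this alone does not account for the count of 2626. What sets these splits apart was not tested. For the interaction the real counts were 0 genes and 0 lists, so that 100 of 100 splits had to reach them and the comparison says nothing about chance. The highest others were 1344 genes and 10 lists, and the split with 1344 genes kept 2 of 6 FLOX mice of the control diet and 5 of 6 of CR in place. Such a split carries part of the genotype difference into the interaction by construction. The 2 other splits that kept these numbers of mice gave 0 and 1 genes, and what sets the split with 1344 apart was not tested.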

How the results depend on the processing

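Counts of genes stayed within 1.5 times the reported count, with directions unchanged for the called lists and named genes, except as follows, and where no reason is given the cause was not tested. Every probe set on its own gave 2539, 3832, 4682 and 4380 probe sets for CR in FLOX, CR in MKO, MKO on the control diet and MKO on CR, since more features are tested. An absolute log2 change of at least 0.5 left 109, 128, 167 and 152 genes by construction. Camera with an estimated correlation called 0, 0, 6 and 9 lists, and with the preset correlation 3 for the interaction. Without the 2 arrays rich in slow muscle transcripts CR in FLOX had 6 lists, and with the clock index as a covariate CR in FLOX had 6 and CR in MKO 3. The index itself rose under CR in the mice labelled MKO, so it may take out part of their diet effect. Without each mouse in turn the lists ranged from 5 to 13, 4 to 8, 13 to 16 and 14 to 17, the genes from 1139 to 1603, 1779 to 2289, 2249 to 3189 and 2103 to 2726, and the interaction stayed at 0 genes and 0 lists by limma and fry. The OXPHOS difference of the mice labelled MKO ranged from -0.25 to -0.22 on the control diet and -0.26 to -0.24 on CR, and the correlations of effects from 0.71 to 0.76 and 0.75 to 0.80. The replicate number as a block gave 1493, 2194, 2882, 2513 and 0 genes and ended the sirtuin call for CR in FLOX (adjusted p = 0.0661) and the lipid call for MKO on the control diet (adjusted p = 0.0624), with the neuromuscular junction gained on CR (adjusted p = 0.0497). These numbers showed little pairing of the mice. The 37 same-number pairs had a median correlation of 0.083 (-0.36 to 0.34), with 16 above 0.1, and other pairs -0.012. Of 26 mice 2 correlated best with a mouse of their own number. The difference between the pairs was not tested, so a weak influence shared by number is not ruled out. Of 149 called results of named genes, the alternatives other than the fold threshold (63 lost) each ended at most 3, and leaving out 1 mouse ended a call 33 times, all of Csrp3, Pfkfb3 or Nnt. The preset correlation ended 9 list calls and gave 8 others. Without a filter the macrophage call for CR in FLOX was lost (adjusted p = 0.0546). The floor near 60 limits all folds of dim genes, and no background limit per array was used.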

Other observations

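Lists of growth and hormone signalling did not pass in the 4 pairwise comparisons. Glucocorticoid target genes had 3 members higher and 0 lower under CR in FLOX mice and 6 higher and 3 lower in the mice labelled MKO (fry adjusted p = 0.499 and 0.533), with Fkbp5 among the latter. The insulin and growth signalling list had 1 higher and 5 lower, and 3 higher and 4 lower (0.499 and 0.546). Genes of glycolysis had 1 higher and 2 lower, and 1 higher and 3 lower (0.484 and 0.986). The list of PGC-1 family and partner regulators had 5 members higher and 3 lower in the mice labelled MKO on the control diet (0.495) and 3 and 3 on CR (0.856). Peripheral nerve markers had 1 member higher and 0 lower under CR in each genotype (0.595 and 0.862).

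The 2 sides of the clock list, that of Dbp and that of Arntl, deviated from their group means in opposite directions over the 26 mice (r = -0.36, permutation p = 0.0441, Spearman's rho -0.40, permutation p = 0.0406). The correlation was -0.33 without the 2 mice farthest out. Within groups r was -0.84 in control-diet FLOX mice (exact permutation p = 0.0278, adjusted p = 0.0556, Spearman's exact p = 0.103) and -0.86 in control-diet MKO mice (exact permutation p = 0.0133, adjusted p = 0.0532). In CR FLOX and CR MKO mice it was 0.01 and 0.34 (exact permutation p = 0.982 and 0.419). Without the 2 mice farthest out r in CR FLOX mice was 0.94 over 4 mice. An index of the 2 sides rose by 0.40 under CR in the mice labelled MKO (exact permutation p = 0.00699, adjusted p = 0.028). The other 3 comparisons did not pass: 0.17 under CR in FLOX mice, -0.26 in the mice labelled MKO on the control diet and -0.03 on CR (exact permutation p = 0.366, 0.187 and 0.82). Times of death were not used here.

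Single genes among the most changed prompted 4 further lists, each written down before its result. For Cd74 the other MHC class II genes had a median of -0.26 (interval -0.85 to -0.06) in FLOX mice and -0.27 in the mice labelled MKO, and 4 of 6 fell in each (fry adjusted p = 8.53e-05 and 4.08e-05). H2-Ab1 and H2-Aa were also members of the macrophage list, and the fall of H2-Ab1 had been seen. The 4 members in none of the fixed lists, tested alone after that, had a median of -0.18 (interval -0.58 to 0.01) and -0.17 (interval -0.63 to -0.02), and 2 of the 4, H2-Eb1 and H2-DMa, fell in each genotype (fry adjusted p = 6e-05 and 4.15e-05). Fewer antigen-presenting cells, or less MHC class II per cell, are hypotheses that flow cytometry of muscle could part. For Eda2r, a p53 target, the other p53 target genes had a median of 0.025 in the mice labelled MKO on the control diet and the list did not pass (fry adjusted p = 0.109 and 0.747 on the 2 diets). Of its 20 members 2 rose and 0 fell on the control diet (Mdm2 and Zmat3) and 3 rose and 0 fell on CR (these and Trp53inp1). For Chac1, a target of ATF4, the other targets had a median of 0.018 under CR in FLOX mice (fry adjusted p = 0.472 and 0.499 in the 2 genotypes). Of 25 members 1 rose (Cth) and 2 fell (Nupr1 and Mars1) in FLOX mice, and 3 rose (Mthfd2, Cth and Eif4ebp1) and 3 fell (Nupr1, Wars and Mars1) in the mice labelled MKO. Under CR in the mice labelled MKO neither Chac1 nor Peg3 itself passed (log2 changes -0.55 and 0.26, limma adjusted p = 0.297 and 0.177). For Peg3 the other 19 imprinted growth genes did not rise on balance under CR. Their median was -0.036 in FLOX mice (interval -0.15 to 0.02) and -0.053 in the mice labelled MKO (interval -0.27 to 0.03), both intervals including 0, while fry gave a direction downward (adjusted p = 0.00968 and 0.00146). In each genotype 1 rose (Igf2) and 4 fell, among them Dcn, a fibroblast gene that is also in the extracellular matrix list (-0.40 and -0.36). The others were Cdkn1c in both, Gnas and Slc38a4 in FLOX mice, and Asb4 and Rian in the mice labelled MKO.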
